A study of Mus musculus with 13 samples.

How the data were processed

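The samples were 13 mouse ChIP-seq libraries, 1 per group, grouped by their titles. NCoR, SMRT and an input were from ESCs, NCoR and SMRT from OSKM cultures at day 9, and H3K27ac from ESCs, MEFs and OSKM cultures at days 5, 9 and 13 with a FLAG control or HDAC3-YF. The submitters' processing notes name the aligner Bowtie2 2.2.0, the peak caller MACS 1.4 and the genome build mm10, without settings. Peaks were deposited as 1 list per library, and every interval in the 12 lists is exactly 200 bp wide. How the called regions were brought to that width is not given in the sources used here, so peak width carries no information and broad H3K27ac domains appear as single or repeated intervals. The read depth of the libraries is not given in the sources used here.

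The deposited score of the H3K27ac lists runs from about 6.2 to a ceiling of 200, and its scale is not stated. The deposited score of the NCoR and SMRT lists is signed. Intervals present in both lists of a cell population carry the same score in both, all NCoR scores lie above -1 and all SMRT scores below 1, so both lists come from 1 joint list and the score is not a peak height. Planned settings that take the top 50% or an equal number of NCoR or SMRT peaks by score were therefore not run. The 5 extreme sites of each list were taken from the high end for NCoR and from the low end for SMRT, a reading of the rule made after the files were examined.

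Peaks were shared where intervals overlapped by at least 1 bp. Where a peak is given as within 1 kb of a site or region, the distance is between centres. Chance levels are means of 1000 circular shifts of a list within chromosomes. NCoR and SMRT peaks of one cell population were merged where they overlapped to give co-repressor sites. ESC-only and MEF-only regions are the H3K27ac peaks of one cell type without an overlapping peak in the other. Shares carry 95% Wilson intervals, and differences between HDAC3-YF and FLAG over the same regions carry 95% intervals from the regions marked in only 1 of the libraries. These intervals treat regions as independent, cover counting error only and say nothing of the spread between cultures. With 1 library per group no test between conditions was made.

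Gene positions came from a RefSeq gene table of GRCm38.p6, which has the coordinates of mm10, with 21887 protein-coding genes on the placed chromosomes. It gives no strand, so the planned 1 kb around transcription start sites was replaced by 1 kb around both annotated ends of each gene. This counts sites at 3' ends too. Since every interval is 200 bp wide, the locus measure is given as the number of H3K27ac peaks in the gene body plus 20 kb on each side, which equals covered length divided by 200 bp. Peaks in these windows can belong to a neighbouring gene. No genome sequence was used here, so the planned search for MYC E-boxes and other motifs at the sites was not made.

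The 9 gene lists were pluripotency, fibroblast and mesenchymal, epithelial, co-repressor complex, MYC targets, clock and nuclear receptors, the reprogramming factors, other lineages and housekeeping. They held 156 genes in all, chosen before the data were examined, and all 156 matched by current symbol. The median difference of a list was placed among 10000 random lists of the same size, drawn from the 100 genes on each side of every member in the ranking by mean H3K27ac locus count. Percentiles describe these libraries and are not tests. In the main setting 330 were computed, and 990 with the settings of 5 kb flanks and equal numbers, over medians, means and site counts, single days and sums, and the other lineages pooled and singly, and no correction was applied. The genes named were fixed by a rule before the data were examined. It takes up to 6 genes per list with the largest ESC to MEF difference, up to 6 with the same sign of HDAC3-YF minus FLAG at all 3 days, up to 6 with a co-repressor site at a gene end, the 10 loci genome-wide with the largest recurrent gain and the 10 with the largest recurrent loss, ranked by the smallest of the 3 day differences, and the introduced factors as checks. Because the score is no height, the genes with a site were taken in the order of the list. Genes named for their HDAC3-YF value at 1 day were chosen from that set after their values were seen. A few genes that the rule takes are not reported here.

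Recurrence across days was compared with 200 shuffles in which each day's differences were permuted within blocks of 200 genes of like mean H3K27ac, a comparison added after the data were examined, as were the counts of these loci by ESC and MEF peaks. Alternatives were the top 50% of each H3K27ac list, the same number of highest-scoring H3K27ac peaks (14251) from each list, an overlap of 50% of the shorter interval, merging of H3K27ac peaks within 1 kb, 2.5 kb around gene ends, sites with both co-repressors and flanks of 5 kb. Added after the data were examined were centres within 1 kb, leaving out chromosome 8, the mean of a list in place of the median, leaving out each day, and the alternatives for single days and single lineages. Overlap and interval code was tested on simulated data, where 94% of 500 simulated intervals held the true difference. In those 500 simulations regions and arms were drawn independently, unlike in the real lists. The result therefore checks the code and not the coverage of the intervals given here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.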

Results

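Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the nuclear receptor co-repressors NCoR and SMRT and the histone mark H3K27ac, an acetylation found at active promoters and enhancers, in mouse cells. The cells were embryonic stem cells (ESCs), mouse embryonic fibroblasts (MEFs) and MEFs carrying the reprogramming factors OCT4, SOX2, KLF4 and c-MYC (OSKM). NCoR and SMRT were mapped in ESCs and in OSKM cultures at day 9. H3K27ac was mapped in ESCs, in MEFs and in OSKM cultures at days 5, 9 and 13 that also received either a FLAG control or HDAC3-YF, a mutant of the histone deacetylase HDAC3 without deacetylase activity. NCoR and SMRT bind and activate HDAC3, and the series asks whether the co-repressors act, together with c-MYC, as a chromatin barrier to reprogramming. Each of the 13 libraries was the only one of its group, and 12 of them had a peak list; the ESC input library was not analysed here. There was therefore no spread between replicates for any value, no test between conditions was made, and the 95% intervals given below cover the counting of regions only. With 3 days, an exact paired test could not have reached a two-sided p below 0.25.

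The ESC lists held 3687 NCoR and 4324 SMRT peaks, and the day 9 lists held 5179 NCoR and 4860 SMRT peaks. The H3K27ac lists held 25499 peaks in ESCs and 26591 in MEFs. The OSKM lists were shorter, with 15645 peaks for FLAG and 16944 for HDAC3-YF at day 5, 16428 and 15241 at day 9, and 15394 and 14251 at day 13. The read depth behind the lists is unknown. The share of H3K27ac peaks at the highest possible score of 200 was 24.4% in ESCs and 25.9% in MEFs, lay between 9.06% and 11.9% in the day 5 and day 9 libraries, and was 1.67% for FLAG and 2.11% for HDAC3-YF at day 13.

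The first comparison asks where the co-repressors sit in pluripotent cells and in cells on the way there. Most NCoR peaks overlapped a SMRT peak of the same cell population. Between ESCs and day 9 cultures only a minority of peaks overlapped. In ESCs 75.0% of the NCoR peaks (interval 73.6 to 76.4%) overlapped a SMRT peak, and at day 9 the share was 78.5% (77.4 to 79.6%). Of the day 9 NCoR peaks, 17.9% (16.9 to 19.0%) overlapped an ESC NCoR peak, and of the day 9 SMRT peaks 19.0% (17.9 to 20.1%) overlapped an ESC SMRT peak. Random placements gave 0.0623% and 0.0719%. Requiring only that peak centres lay within 1 kb raised these shares to 29.5% and 31.9%. The NCoR and SMRT lists of one cell population carried identical scores at all 2743 (ESC) and 4003 (day 9) identical intervals, so the overlap of the co-repressors is that of 1 joint list and not of independent calls.

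Merged into single sites, the lists gave 5245 co-repressor sites in ESCs and 5972 at day 9, and 1185 of the day 9 sites (19.8%) overlapped an ESC site. Day 9 sites lay closer to genes. Of the day 9 sites 75.3% (74.2 to 76.4%) were within 1 kb of an annotated end of a protein-coding gene, against 57.3% (55.9 to 58.6%) of the ESC sites and about 3.46% and 3.44% of random placements. The 2 annotated ends of a gene stand in for its promoter, because the annotation used gives no strand. By gene, 4762 protein-coding genes had a day 9 site at an end and 3191 had an ESC site, and 1747 genes had both. The genes in common were thus 54.7% of the ESC genes and 36.7% of the day 9 genes, where 21.8% of all protein-coding genes had a day 9 site and 14.6% an ESC site. Of the sites themselves, 37.2% of those in ESCs and 33.5% of those at day 9 lay within 1 kb of a site of the other list.

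Most day 9 sites lay within 1 kb of H3K27ac in both cell types at the ends of reprogramming. By direct overlap fewer than 50% met an ESC peak, and fewer than 50% met a MEF peak. An H3K27ac peak within 1 kb was present in both ESCs and MEFs at 84.4% of the day 9 sites (83.5 to 85.3%), in ESCs alone at 2.81%, in MEFs alone at 3.43% and in neither at 9.36%. ESC sites had such peaks in both at 57.9% (56.5 to 59.2%), in ESCs alone at 10.2% and in neither at 28.9%. By direct overlap, 49.1% of the day 9 sites met an ESC peak and 48.8% a MEF peak, against 36.3% and 32.7% of the ESC sites. The 1185 day 9 sites that overlapped an ESC site had an ESC H3K27ac peak within 1 kb at 96.3% and overlapped one at 62.1%.

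**Figure D1:**
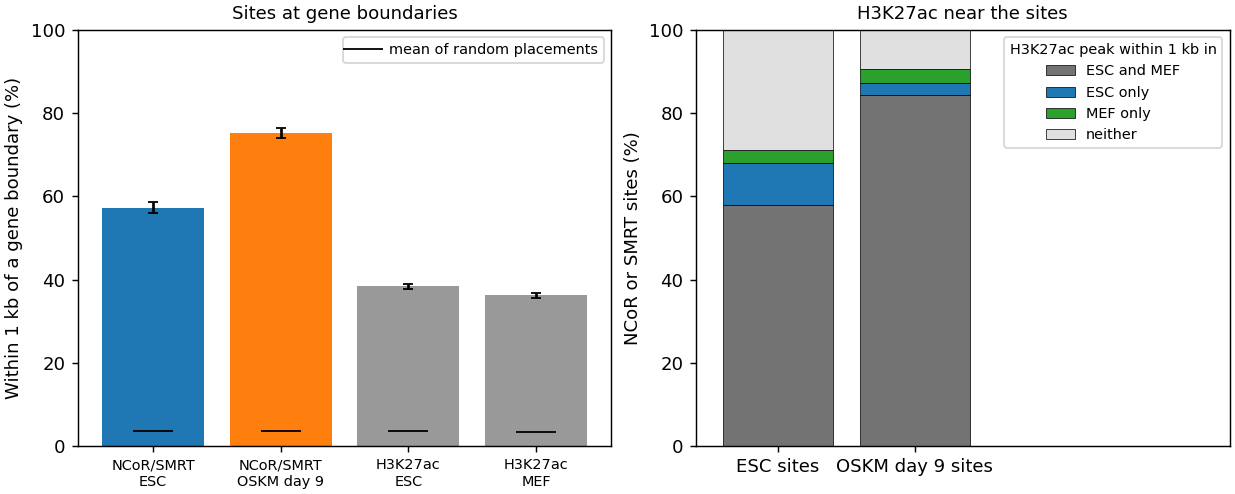
Left, share (%) of co-repressor sites and of H3K27ac peaks within 1 kb of an annotated end of a protein-coding gene; bars are single libraries or merged lists, error bars are 95% Wilson intervals and black dashes the mean of 1000 random placements. Right, share (%) of the co-repressor sites with an H3K27ac peak within 1 kb in ESCs and MEFs, in one of them or in neither. Day 9 sites stand at 75.3% near gene ends against 57.3% for ESC sites, and at 84.4% near H3K27ac of both cell types against 57.9%.

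Among the gene lists fixed in advance, no list carried day 9 sites at more genes than the range of matched lists. A day 9 NCoR or SMRT site lay at an end of 10 of the 20 growth genes driven by MYC, against a mean of 7.05 in random lists matched on H3K27ac (percentile 90.9). They included the nucleolar proteins Ncl, Nop56, Nop58 and Fbl, the RNA helicase Ddx21 and the polyamine enzyme Odc1. In ESCs 1 of the 20, Ncl, had a site (random mean 4.42, percentile 2.825). Pluripotency genes had day 9 sites at 3 of 30 (random mean 6.60, percentile 4.49) and ESC sites at 4 of 30. The day 9 genes were Sox2, Klf2 and Fgf4, and the ESC genes were Klf2, Klf5, Utf1 and Fgf4. Sox2 is one of the introduced factors, and peaks over its exons can come from introduced copies.

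Fibroblast and mesenchymal genes had day 9 sites at 6 of 30 (random mean 8.51). Among them were the transcription factors Twist1 and Snai1, the cytoskeletal gene Vim and the matrix genes Fn1 and Fbn1. The list had ESC sites at 2 of 30 (random mean 5.69, percentile 3.5), of which 1 was Zeb1. Epithelial genes had day 9 sites at 3 of 20 (random mean 5.52) and ESC sites at 5 of 20 (random mean 3.77, percentile 76.2). Clock and nuclear receptor genes had day 9 sites at 4 of 15, namely Nr1d1, Nr1d2, Per2 and Nr1h2, of which the REV-ERB receptors encoded by Nr1d1 and Nr1d2 are themselves partners of NCoR. The counts at day 9 were 4 of 8 for housekeeping genes, 2 of 6 for genes of the co-repressor complex, 2 of 4 for the reprogramming factors (Sox2 and Myc) and 0 of 26 for markers of other lineages. All of these day 9 counts, those of MYC targets included, lay within the central 95% of the matched lists.

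The site with the highest NCoR-side score at day 9 lay in Banp (chromosome 8, 121950471 to 121950670, score 3.31), followed by sites near Spred2 and in Zcchc8. The SMRT-side extremes at day 9 lay in Nkx6-1 (chromosome 5, 101664256 to 101664455, score -2.85), Trib2 and Ugdh. In ESCs the extremes lay near E330021D16Rik on the NCoR side (score 2.90) and in LOC115488765 on the SMRT side (score -3.24), followed by Fgf18, Mok, Prkce and Setd7 (score -3.14 each). The score is the authors' own, its meaning is not stated, and it is used here only to rank sites within a list.

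ESCs and MEFs were compared next at marker genes, to give the scale for the reprogramming cultures. H3K27ac peaks were counted in each gene body with 20 kb on each side. Of the 30 pluripotency genes 28 had more peaks in ESCs than in MEFs, with a median difference of 3 peaks, above all 10000 matched lists. The orphan nuclear receptor gene Esrrb had 11 peaks in ESCs and 0 in MEFs, the transcription factor gene Tfcp2l1 had 9 and 0, Klf2 had 9 and 2, and the methylcytosine dioxygenase gene Tet2 had 10 and 1. Of the 30 fibroblast genes 29 had more peaks in MEFs, with a median difference of -2 peaks, below all matched lists. Fibrillin (Fbn1) and Runx1 had 12 peaks each in MEFs against 0 and 1 in ESCs, the mesenchymal regulator Prrx1 had 7 and 0, and Col1a1 had 7 and 1. The exception was fibronectin (Fn1), with 1 peak in MEFs and 7 in ESCs.

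Epithelial genes had more peaks in ESCs at 12 of 20 and fewer at 3, with E-cadherin (Cdh1) at 12 peaks in ESCs and 2 in MEFs. The median differences were 1.5 peaks for the 6 co-repressor complex genes, -1 for clock and nuclear receptor genes, and 0 for MYC targets, housekeeping genes, the reprogramming factors and markers of other lineages.

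The second comparison asks how H3K27ac differed between cultures with the inactive deacetylase and FLAG cultures during reprogramming. With HDAC3-YF more of the ESC-only regions and fewer of the MEF-only regions were acetylated at days 9 and 13. ESC-only regions are the 15970 ESC peaks that overlap no MEF peak, and MEF-only regions the 17062 MEF peaks that overlap no ESC peak. The share of ESC-only regions overlapping a peak was 8.56% for FLAG and 9.68% for HDAC3-YF at day 9, a difference of 1.12 percentage points (0.669 to 1.57), and 8.41% and 11.2% at day 13, a difference of 2.77 points (2.28 to 3.25). At day 5 the shares were 8.85% and 9.09%, and their difference of 0.232 points had an interval from -0.202 to 0.665. When any peak within 1 kb of these regions was counted, the differences were 1.35 points (0.935 to 1.76) at day 5, 0.996 (0.559 to 1.43) at day 9 and 1.53 (1.02 to 2.04) at day 13.

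MEF-only regions went the other way. FLAG peaks overlapped 16.8% of them at day 9 and HDAC3-YF peaks 12.9%, a difference of -3.97 points (-4.49 to -3.46), and at day 13 the shares were 14.1% and 9.91%, a difference of -4.18 points (-4.69 to -3.67). At day 5 they were 12.6% and 12.9%, with a difference of 0.299 points (-0.183 to 0.780). Within 1 kb the differences were 0.557 points at day 5, -4.32 at day 9 and -6.40 at day 13. Of the MEF-only regions 311 were acetylated in both the day 9 and the day 13 FLAG library and in neither HDAC3-YF library of those days, and 73 showed the opposite. For ESC-only regions 151 were acetylated in both HDAC3-YF libraries and neither FLAG library, and 86 showed the opposite. Few ESC-only regions were set apart at all 3 days, with 21 in the HDAC3-YF libraries alone and 19 in the FLAG libraries alone, and 76.8% had no peak in any of the 6 libraries.

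The FLAG libraries of different days differed from each other as well. Their shares of MEF-only regions spanned 4.202 points between days, more than either HDAC3-YF difference, while their shares of ESC-only regions spanned 0.445 points, less than the differences at days 9 and 13. The HDAC3-YF libraries spanned 2.09 points in ESC-only and 3.03 points in MEF-only regions. Days differ by time of reprogramming as well as by culture, so none of these spans is one of cultures alone. With the same number of highest-scoring peaks taken from every list, the day 5 differences became -1.79 points for ESC-only and -2.38 points for MEF-only regions, and the ESC-only differences at days 9 and 13 became 3.21 and 6.32 points.

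**Figure D2:**
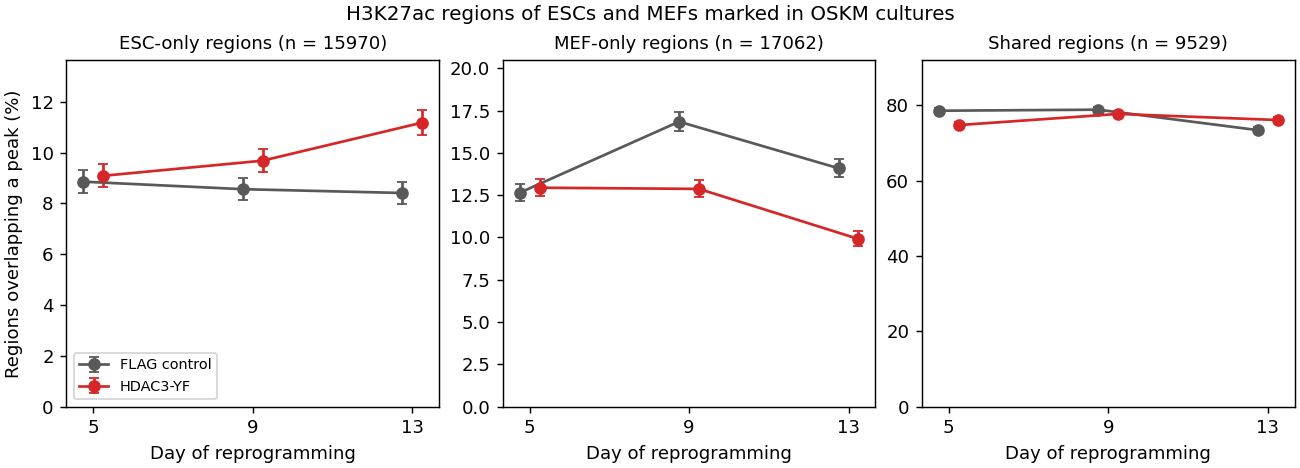
Share (%) of ESC-only, MEF-only and shared H3K27ac regions that overlap a peak of each OSKM library, by day of reprogramming; each point is 1 library and error bars are 95% Wilson intervals, which cover counting only. HDAC3-YF lies above FLAG for ESC-only regions at day 13 (11.2% against 8.41%) and below it for MEF-only regions (9.91% against 14.1%).

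In regions acetylated in both ESCs and MEFs and at the co-repressor sites, the sign of the difference was not the same at all days. The 9529 shared regions were acetylated less often with HDAC3-YF at day 5, by -3.81 points (-4.62 to -3.00), and at day 9, by -1.12 points (-1.95 to -0.301), and more often at day 13, by 2.68 points (1.77 to 3.59). When any peak within 1 kb was counted, the differences were -1.81, -1.15 and 0.336 points, the last with an interval from -0.372 to 1.04. FLAG libraries of different days spanned 5.42 points there. At the day 9 co-repressor sites the FLAG share was 49.1% at day 5, 48.5% at day 9 and 47.4% at day 13. The HDAC3-YF share differed by -3.05 points (-4.07 to -2.03) at day 5, by -0.536 points (-1.59 to 0.517) at day 9 and by 1.59 points (0.503 to 2.68) at day 13. With centres within 1 kb the day 13 difference at the sites was 0.385 points (-0.275 to 1.05). At the ESC co-repressor sites the differences were -2.08 points at day 5, -0.191 at day 9 and 3.11 (2.02 to 4.19) at day 13, and within 1 kb they were -1.53, -0.725 and 3.70 (2.89 to 4.51).

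At marker genes the fibroblast list differed between HDAC3-YF and FLAG, in opposite directions at day 5 and day 9. At day 9 peaks were fewer with HDAC3-YF at 17 of the 30 fibroblast genes, more numerous at 1 and equal at 12, with a median of -1 peak (percentile 0.005 of the matched lists). With flanks of 5 kb, and with equal numbers of peaks, 13 genes were lower and 1 higher at day 9, and the median was 0. The mean, which is not tied to whole peaks, was -0.5 in both settings and stayed at percentiles 0.325 and 0. At day 13 peaks were fewer at 11 genes and more numerous at 2, with a median of 0 and a mean of -0.433 (percentile 0.665). At day 5 peaks were fewer at 3 genes and more numerous at 12. The day 5 median was 0, and the mean was 0.433 peaks (percentile 99.11). Fbn1 had 4 peaks with FLAG and 7 with HDAC3-YF at day 5, 5 and 2 at day 9, and 2 and 1 at day 13. Twist1 had 3 and 1 at both day 9 and day 13, Snai1 had 2 and 1 at both days, and vimentin (Vim) had 2 and 1, then 3 and 1. Summed over the 3 days the list had a median of -1 peak (percentile 0.355), with 16 genes lower and 4 higher. This median was 0 with flanks of 5 kb or without day 9 or day 13.

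Epithelial genes had more peaks with HDAC3-YF at day 13 at 11 of 20 and fewer at 4, with a median of 1 peak (percentile 99.95), at day 9 they split evenly, with 6 higher and 6 lower, and at day 5 there were 2 higher and 5 lower. With flanks of 5 kb the day 13 median was 0, with 8 higher and 4 lower, and the day 13 mean, 0.35 peaks, lay at percentile 97.1. Cdh1 had 2 peaks with FLAG and 4 with HDAC3-YF at day 9, and 3 and 4 at day 13. The tight junction genes Cldn3 and Cldn4 had 0 and 2, and 1 and 3 peaks, at day 13. Ap1m2, an adaptor subunit of epithelial sorting, was lower with HDAC3-YF at all 3 days, with 4 and 2 peaks at day 5, 3 and 2 at day 9, and 4 and 1 at day 13. Over the 3 days the epithelial median was 0 (percentile 51.8).

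Pluripotency genes had far fewer peaks in both arms than in ESCs. The 30 genes held 141 peaks in ESCs and 28 in MEFs. With FLAG and HDAC3-YF they held 28 and 24 at day 5, 33 and 34 at day 9, and 29 and 37 at day 13. At day 5 peaks were fewer with HDAC3-YF at 3 genes and more numerous at 0. At day 13 peaks were more numerous with HDAC3-YF at 10 genes, fewer at 4 and equal at 16, and the median over the 3 days was 0 (percentile 50.4). Esrrb and Dppa5a had 0 peaks with FLAG and 1 with HDAC3-YF at day 13, Utf1 had 0 and 2, Nr5a2 had 1 and 0, Klf2 had 2 and 1, and Tfcp2l1 had 0 in all 6 OSKM libraries.

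The 3-day medians of the other 6 lists all lay within the central 95% of the matched lists. They were 0 for clock and nuclear receptor genes (percentile 55.8), MYC targets (49.3) and markers of other lineages (50.0), 0.5 for the co-repressor complex (79.7), and -0.5 for both housekeeping genes (15.1) and the reprogramming factors (34.8). Of the single lineages within the markers of other lineages, 4 had medians of 0, but the 4 endothelial genes had a median of -1.5 peaks (percentile 0.69), with 2 lower and 0 higher, and the 5 primitive endoderm genes a median of 1 peak (percentile 97.88), with 3 higher and 0 lower. Without day 9 the endothelial percentile was 8.96, and without day 13 that of primitive endoderm was 50.2. For the clock and nuclear receptor list the mean, 1.53 peaks, lay at percentile 99.95 where the median did not, with 7 genes higher and 4 lower. Ppard had 3 peaks with FLAG and 8 with HDAC3-YF at day 13, Thra had 5 and 10 and Nr1d1 3 and 8 at day 5, and Rarg was higher at all 3 days, with 1 and 3, 3 and 4, and 2 and 3. Thra and Nr1d1 are neighbours and share peaks. For these 9 lists 63 percentiles of medians were computed for HDAC3-YF against FLAG in the main setting, and 315 with the single lineages and with the settings of 5 kb flanks and equal numbers.

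**Figure D3:**
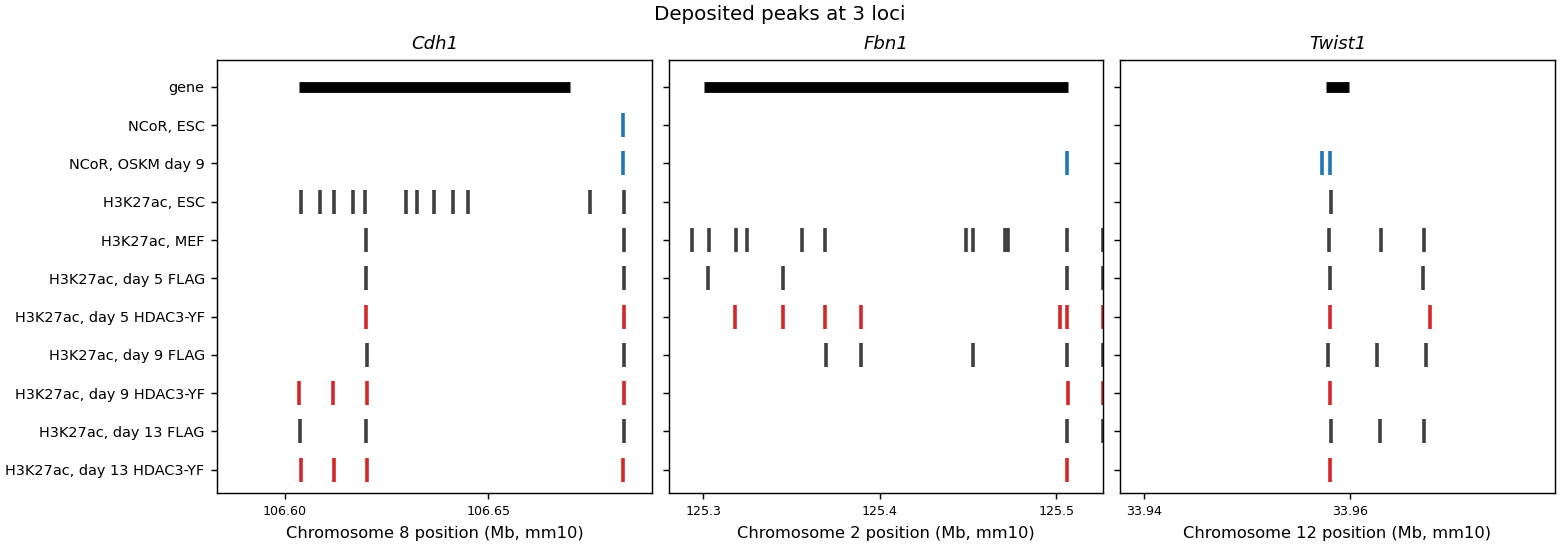
Positions of deposited peaks (vertical ticks, 1 row per library) along 3 loci with 20 kb on each side, in Mb of mm10; the black bar is the annotated gene, blue ticks are NCoR peaks, black ticks H3K27ac peaks and red ticks H3K27ac peaks of HDAC3-YF libraries. At Cdh1 the ESC library has 12 peaks and the day 9 libraries 2 (FLAG) and 4 (HDAC3-YF). At Twist1 the counts at day 13 are 3 (FLAG) and 1 (HDAC3-YF).

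Over all protein-coding genes, loci with fewer H3K27ac peaks with HDAC3-YF at every day outnumbered shuffled data, and loci with more peaks did not. Peaks were fewer with HDAC3-YF at all 3 days at 316 gene loci, against a mean of 178 and a highest value of 210 in 200 shuffles of the day differences among loci of like H3K27ac. They were more numerous at all 3 days at 139 loci, against a mean of 124 and a highest value of 152. Neighbouring genes share peaks, so the loci are not independent. Of the 316 loci 163 had more peaks in MEFs than in ESCs and 80 fewer, and of the 139 loci 27 had more and 76 fewer. Of all 21887 protein-coding genes 4975 had more peaks in MEFs, 6078 had fewer and 10834 had equal numbers.

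The 10 loci with the largest recurrent negative difference included 9 with more peaks in MEFs than in ESCs. The forkhead factor gene Foxp1 had 26 peaks in MEFs and 3 in ESCs, and in OSKM cultures 15 with FLAG and 11 with HDAC3-YF at day 5, 15 and 9 at day 9, and 7 and 5 at day 13. Zbtb20 had 20 and 18, 15 and 7, and 7 and 4 at the same days. Slit3 had 9 and 2 at day 9 and 5 and 2 at day 13, Ets1 had 5 and 1, then 4 and 2, and the homeobox gene Hoxb3 had 6 and 3, then 9 and 4. Ctif, Tbc1d1, Syn3, Nfix and Lhpp made up the remainder. The 10 loci with the largest recurrent positive difference included 7 with more peaks in ESCs. The splicing regulator gene Rbfox2 had 4 peaks with FLAG and 11 with HDAC3-YF at day 5, 6 and 8 at day 9, and 3 and 5 at day 13. The neighbouring metallothionein genes Mt1 and Mt2, which share their peaks, had 3 and 5, 3 and 5, and 2 and 4, and the glucose transporter gene Slc2a1 had 2 and 3, 2 and 3, and 1 and 5. Igdcc4, Fdft1, Rai14, Etl4, Frmd8 and H4c6 completed the set.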

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

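Within this part, the comparison with the spread between FLAG days was chosen after its values were seen, and the comparison at equal numbers of peaks before.

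Regions acetylated in both ESCs and MEFs and the day 9 co-repressor sites stood out because the sign of HDAC3-YF minus FLAG changed between days. For shared regions the difference was -3.81 points at day 5, -1.12 points at day 9 and 2.68 points at day 13, and for day 9 co-repressor sites it was -3.05 points at day 5 and 1.59 points at day 13. With peaks within 1 kb counted, the day 13 differences were 0.336 points (-0.372 to 1.04) for shared regions and 0.385 points (-0.275 to 1.05) for sites, so without direct overlap the day 13 gain was not clear of 0. The ESC co-repressor sites kept a day 13 difference of 3.70 points (2.89 to 4.51) under that count. The change between days was not tested, since each day has 1 library per arm. FLAG libraries of different days differed by up to 5.42 points in shared regions, more than any of the 3 differences there. At the day 9 sites they differed by up to 1.64 points, less than the difference at day 5 and more than that at day 13. At the ESC co-repressor sites the FLAG libraries differed by up to 0.419 points. This was smaller in size than the differences of -2.08 points at day 5 and 3.11 points at day 13, and larger than that of -0.191 at day 9. The HDAC3-YF libraries of different days differed there by up to 5.19 points.

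The main pattern was more ESC-only and fewer MEF-only regions acetylated with HDAC3-YF at days 9 and 13. It was weighed against the number of peaks called and against variation between cultures or libraries. The arms also differed in where their peaks lay. Within 1 kb of gene ends lay 52.9% of FLAG and 47.3% of HDAC3-YF peaks at day 5. These shares were 51.5% and 54.0% at day 9, and 54.5% and 60.9% at day 13. Whether this difference contributes to the pattern was not tested. A difference in the number of peaks called is argued against as the whole cause, since all 4 differences (both region classes at both days) kept their sign beyond their intervals when every list was limited to its 14251 highest-scoring peaks. That limit also cut the ESC and MEF lists and redrew each region class to 6975 regions, so the comparison is not over the same regions. It also moved the day 5 differences, to -1.79 points for ESC-only and -2.38 points for MEF-only regions. Variation between cultures or libraries unrelated to HDAC3-YF cannot be told apart from an effect of the mutant. Only 2 of the 4 differences, both in ESC-only regions, were larger than any difference between 2 FLAG libraries, and the larger MEF-only differences were not. Days differ by time of reprogramming as well as by culture, so this spread is not one of cultures alone. An effect of the inactive deacetylase therefore stays open as a hypothesis, and replicate cultures of 1 day would be needed to test it.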

How the results depend on the processing

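Alternatives named here as centres within 1 kb, without chromosome 8, the mean of a list and the sums without 1 day were chosen after the data were examined. No paired analysis was possible within a day because each arm has 1 library. Pairing by day gives 3 pairs, for which the smallest two-sided exact p is 0.25, and no test was made. Merging H3K27ac peaks within 1 kb left all 9 HDAC3-YF differences within their intervals. The differences at days 9 and 13 kept their sign in ESC-only and MEF-only regions under every alternative run; those at day 5 did not. The cause was not tested except where stated.

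With an overlap of 50% the day 9 peaks also bound in ESCs were 11.5% for NCoR and 12.3% for SMRT. The differences became -0.456 (day 5) and 2.28 (day 13) points for ESC-only regions, -0.622, -2.59 and -2.50 points at days 5, 9 and 13 for MEF-only regions, and -1.83 points for co-repressor sites at day 5. With centres within 1 kb, which widens what counts as shared, NCoR peaks shared with SMRT were 77.7% in ESCs and 81.7% at day 9, and day 9 peaks also bound in ESCs were 29.5% for NCoR and 31.9% for SMRT. The differences were 1.67 (day 5) and 2.13 (day 13) points for ESC-only regions, -4.88 (day 9) and -7.13 (day 13) for MEF-only regions, and -1.66 (day 5) and 0.385 (day 13) for sites. Without chromosome 8 the NCoR share also bound in ESCs was 16.8%. Within 2.5 kb of gene ends lay 81.5% of day 9 sites, and within 1 kb lay 80.2% of sites with both co-repressors.

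With the top 50% of each H3K27ac list the differences were -0.376 points for ESC-only regions at day 5, and 0.938, -5.10 and -4.94 points for MEF-only regions at days 5, 9 and 13. With equal numbers of peaks they were -1.79, 3.21 and 6.32 points for ESC-only and -2.38, -4.92 and -5.10 points for MEF-only regions at days 5, 9 and 13. Both settings also redraw the region classes, as do the 50% overlap, the merging and the centres within 1 kb. ESC-only regions numbered 15970 in the main setting, 18844 with 50% overlap and 13493 with centres within 1 kb. The differences within 1 kb given in Results keep the regions of the main setting, so they are not the same as those given here.

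The percentile of the fibroblast list, 0.355, became 49.9 with flanks of 5 kb, 49.0 without day 9 and 50.1 without day 13, each with a median of 0. The percentile of the clock and nuclear receptor list, 55.8, became 97.9 with flanks of 5 kb, 99.95 with the mean, 99.0 without day 5 and 98.8 without day 13. The 3-day medians of the other 7 of the 9 lists lay within the central 95% of matched lists in every alternative applied alone, but flanks of 5 kb and leaving out day 5 combined put the epithelial list at 99.74. Single days and single lineages were added here after the data were examined. The fibroblast value at day 9, 0.005, became 50.005 with flanks of 5 kb and 49.995 with equal numbers of peaks, both with a median of 0, where the mean of -0.5 stayed at 0.325 and 0. The epithelial value at day 13, 99.95, became 49.965 with flanks of 5 kb, with a median of 0, and 97.12 with the mean. The endothelial value over 3 days, 0.69, became 2.525 without day 5 and 8.96 without day 9, and that of primitive endoderm, 97.88, became 50.235 without day 13. Not run were the settings that rank NCoR or SMRT peaks by score, since the score is not a height, and all settings of the E-box search, for which no genome was used. Depth is unknown, and the low share of peaks at the score ceiling at day 13 limits comparisons between days more than those within a day.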

Other observations

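Of the tests in this part, those on introduced gene copies were chosen after their results were seen; those on chromosome 8, on regions near co-repressor sites and on MYC targets were set before.

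Some genes of the co-repressor complex had more H3K27ac peaks in ESCs than in MEFs. The gene of NCoR, Ncor1, had 12 H3K27ac peaks in ESCs and 2 in MEFs, and Tbl1xr1, which encodes a shared subunit of the complexes, had 12 and 1. In the OSKM libraries both had 1 or 2 peaks.

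Chromosome 8 held 13.1% of the ESC co-repressor sites but 5.51% of the day 9 sites, 6.51% of the ESC H3K27ac peaks and 5.32% of the MEF H3K27ac peaks. A few dense clusters are argued against, because they would need more than 50% of the excess in the 5 densest windows of 1 Mb. These windows held 101 sites in all, a number equal to 24.04% of the excess of 420.2 sites. Of 130 windows 105 held a site. An interval of 20.2 to 28.4% was added after the value was seen, and it spans the lower bound named in advance as the opposite outcome. It treats all 101 sites as part of the excess, which they need not be. Extra copies of chromosome 8 in the ESC culture, which would raise background there, may account for the excess and predict more sites away from active chromatin. The share of chromosome 8 sites within 1 kb of an ESC H3K27ac peak was 65.5% (61.8 to 68.9%) against 68.5% (67.1 to 69.8%) elsewhere, so the intervals overlap and the explanation stays open. Chromosome 8 held 15.7% of the ESC sites in both lists, 9.12% of those with NCoR only and 10.8% of those with SMRT only. Chromosome X held 0.210% of the ESC sites and 0.569% of the day 9 sites, against 2.31% of the ESC H3K27ac peaks. For chromosome 8 no cause beyond dense clusters and extra copies was tested, and for chromosome X none was.

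All 24 pairs of an OSKM H3K27ac library and a reprogramming factor gene had a peak in the gene body, and day 9 co-repressor sites lay in the bodies of Sox2, Klf4 and Myc but not Pou5f1. ESCs, whose labels name no introduced factors, also had a site in the Klf4 body. Klf4 had no H3K27ac peak in its body in ESCs or MEFs and 1 in each OSKM library. Integrated cDNA copies of the 4 reprogramming factors may give such peaks, but MEFs also had body peaks in Pou5f1, Sox2 and Myc, which keeps the question open. Their highest scores in MEFs were 11.41, 7.09 and 175.03, against the ceiling of 200 in all OSKM libraries for Sox2, in all but FLAG at day 9 (113.57) for Pou5f1, and at days 5 and 9 for Myc. For Hdac3 a peak more than 1 kb inside the gene was found in 2 of the 3 HDAC3-YF libraries and in 0 FLAG libraries, but also in ESCs, and the libraries are too few to tell whether integrated cDNA copies of HDAC3-YF are seen.

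ESC-only regions within 10 kb of a day 9 co-repressor site were acetylated in 18.6% with FLAG and 23.8% with HDAC3-YF at day 13, a difference of 5.18 points (3.49 to 6.87). Farther regions had 6.84% and 9.24%, a difference of 2.40 points (1.90 to 2.89). The hypothesis that HDAC3-YF acts more at regions near the co-repressors predicted the larger difference in points, and the excess was 2.78 points. The ratios of HDAC3-YF to FLAG, computed after that result, were 1.28 (1.18 to 1.39) near sites and 1.35 (1.27 to 1.44) farther away. Relative to the FLAG level of the same day, the HDAC3-YF share was thus not higher near sites than farther away. The excess may therefore follow from the higher level near sites. At day 5 the differences were -0.424 points (-1.96 to 1.11) near sites and 0.332 (-0.109 to 0.774) farther away. At day 9 they were 2.07 points (0.433 to 3.71) and 0.975 (0.519 to 1.43).

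The hypothesis that day 9 co-repressor sites prefer MYC target genes was not decided, since 10 of 20 genes lay at percentile 90.9 of the matched lists, short of the top 2.5% set in advance.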
